A study of Mus musculus with 8 samples.

How the data were processed

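C/EBPα binding was measured by CUT&RUN, in which an antibody-tethered nuclease releases the DNA next to a bound protein, in sorted mouse bone marrow progenitors (Lin− KIT hi-int FLT3+). The cells carried 1 of 3 genotypes of the Zeb2 -165 kb enhancer, which the labels call WT, DC and DE. Per the labels' protocols, 3 µL of anti-C/EBPα or 1 µL of control IgG was used, digestion lasted 30 minutes, 14 PCR cycles were run, fragments of 150 to 350 bp were enriched and reads were 150 bp paired-end. Each genotype had 2 anti-C/EBPα libraries, 1 in each of 2 batches given by the labels, and replicate 1 is batch 1 throughout. The 2 IgG libraries came from WT cells and were not analysed here, so no background could be measured in them. The labels do not say whether replicates came from separate animals, so p-values of tests between libraries measure the spread between these libraries. Fisher's exact tests count genes or regions, and their p-values hold no spread between libraries.

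Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2, SAMtools, MACS2 2.2.9.1 and HOMER, with genome build mm10; the versions of the others and the role of each were not given. The deposited peak lists, 1 per anti-C/EBPα library, were named with a q of 0.1, and the smallest −log10 q in each list was checked against it. In the deposited lists the authors give a fold enrichment at the summit over the local background, which is a ratio, together with the −log10 p-value and −log10 q-value of each peak. The deposited score is 10 times the −log10 q, cut to a whole number. The notes do not state whether the IgG libraries served as control for the peak calls. The deposited merged table, made with HOMER per its file header, holds coordinates of 259446 regions and no measurement, so its remaining column has no unit and the test of read counts between genotypes that had been planned was not made. The files analysed here give no read totals, so sequencing depth is unknown.

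Peaks of the 6 lists that overlapped by at least 1 bp were merged with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 into 259446 regions, and a region counted as called in a library that had a peak in it. Coordinates are 1-based mm10. Gene positions came from a table of the same assembly with 21883 protein-coding genes, which gives both ends of a gene but neither strand nor transcripts. Distances that had been planned from a transcription start were therefore taken from the nearer annotated gene end, and promoter, exon and intron classes were replaced by within 1 kb of a gene end, inside a gene and between genes. The enhancer window was centred 165 kb beyond the Zeb2 gene end at position 45117442, with 10 kb to either side, and the locus ran from 300 kb beyond that end to 50 kb beyond the other. No genome sequence was at hand, so the planned motif search was not run.

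Genotypes were compared by peak number (exact permutation test of log2 number, scipy 1.17.1), by Jaccard overlap between libraries (exact permutation of genotype labels), and by counting the regions called in both libraries of one genotype and neither of another. Those counts were set beside the counts from the other 2 ways to pair the same 4 libraries. For 11 gene lists of cell types, holding 182 genes of which 3 (Csf1r, Klf4 and Zeb2) stand on 2 lists, genes with a region called in both WT libraries within 10 kb were compared with all other protein-coding genes by Fisher's exact test. The lists were neutrophil and monocyte, cDC1, cDC2, pDC, stem and progenitor, B lymphoid, T and NK, erythroid and megakaryocyte, mast, basophil and eosinophil, non-haematopoietic, and housekeeping genes. Adjustment was by Benjamini-Hochberg over the lists. Named regions followed a rule: the 10 with the best worse-of-2 rank by −log10 q in each set called in one genotype only, the 10 strongest in WT, all Zeb2 locus regions, and up to 4 members per list by the rank of their best WT region, plus up to 3 without one.

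The number of fragments over each summit (the pileup) and the local background were recovered from the deposited fold and p-value. With pileup k and background λ, the fold is (k + 1)/(λ + 1) and the p-value is a Poisson tail, so 1 whole k solves both. At a tolerance of 5% of the step between whole numbers, 99.99% of the peaks had a solution in the list where the fewest did. The smallest background in a library is called its floor. Recovered pileups were scaled between libraries by the median log2 difference over the 23480 regions called in all 6 libraries. They were compared there on the log2 scale with limma 3.58.1 (R 4.3.3; trended variance, Benjamini-Hochberg, 0.05), once without and once with batch as a term. Regions within 10 kb of listed genes were tested as sets with camera. The batch term is a valid pairing by the labels. Deviations of the batches correlated across regions with r of 0.55 between WT and DC, 0.41 between WT and DE and 0.38 between DC and DE; regions are not independent replicates. The limma step was tested on simulated data of 23480 regions for DC against WT. With batch as a term it found 54% of 100 regions changed 2-fold and 92% of 100 changed 4-fold, with 11 false calls, and without the term it found 0%. The simulated regions had the batch shifts of the real fit and, beyond counting error, a common spread. Real regions may differ in spread, so these rates need not hold for them. From the fit with the batch term, up to 10 regions with the smallest adjusted p in each direction were named, with the called regions of the lists. The fits were repeated with the genotype labels of the pair exchanged in batch 2. That exchange is 1 relabelling and puts a difference shared by both batches into the residual spread, so its count is no rate of false calls.

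The samples, groups, gene lists, windows, tests of peak calls and the alternatives to them (a −log10 q of at least 2, lists of equal length at 50221 peaks, summits within 200 bp, gene windows of 1 and 50 kb, a 5 kb enhancer window, the authors' merged table, leaving out each replicate number, and blocking by batch) were fixed before the data were examined. The pileup recovery, its scalings, the limma fits with their leave-one-out runs, the use of gene ends and the peak distribution alternatives were chosen after the data were seen. Confidence intervals are at 95%, exact for Poisson counts and for the ratio of 2 of them, and cover counting error only, since reads without molecular identifiers are not independent molecules. A pileup compares libraries only after scaling, and fold and −log10 q were compared within a list only.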

Results

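C/EBPα, a transcription factor of the myeloid lineages, was profiled by CUT&RUN in sorted bone marrow Lin− KIT hi-int FLT3+ progenitors of mice with 3 genotypes of the Zeb2 -165 kb enhancer. The genotypes were WT and the variants named DC and DE in the labels, with 2 libraries each, 1 per batch. Zeb2 encodes a zinc-finger repressor of dendritic cell and myeloid fate choice, and the series title places the enhancer in the specification of cDC1, the dendritic cells that cross-present antigen. The WT lists held 82080 and 56940 peaks in batches 1 and 2, the DC lists 169943 and 50221, and the DE lists 52474 and 57441. Read totals were not given, so the depth is unknown. The libraries were described by the summit pileup, the number of fragments over a summit, which mixes depth with enrichment. The median pileup at regions shared by all libraries was 34 and 34 in WT, 58 and 24 in DC and 42 and 32 in DE. The background floor was 1.33 and 0.902 in WT, 1.11 and 0.368 in DC and 1.53 and 0.408 in DE. DC replicate 1 thus had a higher pileup but a lower floor than WT replicate 1. Replicates are numbered by batch.

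In WT progenitors C/EBPα lay near every neutrophil and monocyte gene listed. All 31 genes of that list, led by Fes, Spi1 (the factor PU.1), Trib1 and Cx3cr1, had a region called in both WT libraries within 10 kb of a gene end, against 52.9% of other protein-coding genes (Fisher's exact test, adjusted p = 5.7e-08). The stem and progenitor list had 18 of 20 occupied (adjusted p = 0.00212), led by Fli1, Myc, Ikzf1 and Flt3, and Erg was unoccupied. All 15 housekeeping genes were occupied (adjusted p = 0.000461), so an occupied gene end was not particular to myeloid genes. Non-haematopoietic genes were occupied less often than other genes, with 4 of 20 (adjusted p = 0.00888), and Alb, Ttr and Ins2 had no such region. The other lists did not differ from other genes: 10 of 15 cDC1 genes, 10 of 15 pDC genes and 10 of 15 B lymphoid genes (adjusted p = 0.494 each). Nor did 9 of 14 cDC2 genes (0.598), 9 of 15 erythroid and megakaryocyte genes (0.678), 4 of 10 mast, basophil and eosinophil genes (0.649) and 8 of 15 T and NK genes (1.0). Among cDC1 genes, Nfil3, Zbtb46, Ppt1 and Clec9a had the strongest WT regions, and Cadm1, Tlr3 and Itgae had none. In both DC libraries 31 of 31 neutrophil and monocyte genes and 20 of 20 stem and progenitor genes were occupied, and in both DE libraries 30 of 31 and 20 of 20. Tests were two-sided, and the stem and progenitor call ended with a window of 1 kb (45% occupied, adjusted p = 0.347). At 50 kb the non-haematopoietic call ended (50%, adjusted p = 0.0862) and all cDC2 genes were occupied (100%, adjusted p = 0.0445).

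The strongest WT regions by −log10 q differed widely in fold over local background. Of the 10 best-ranked, 4 had a summit fold under 2 in both WT libraries, and their nearest genes were far off (Lrrc4c at 1035 kb, Alkbh8 at 334 kb and Gm2244 at 116 and 117 kb). Others, in Hjurp, Megf11 and Pik3ap1 and nearest to Mdm1 (37.6 kb away) and Kntc1 (9.93 kb away), had WT replicate 1 folds from 60.7 to 182. Limiting the ranking to regions with a background under 5 times the floor, a limit chosen after the values were seen, put Pik3ap1, an adaptor of PI3 kinase, first. Regions of Ptges, Cdkl3, Ets2 (7.58 kb away), Mknk1 and Ptgs2 (56.5 kb away) followed. Across the 6 libraries a mean of 16.0% ± 4.04 (SD, n = 6) of peaks lay within 1 kb of a gene end, 41.9% ± 0.627 inside genes and 42.1% ± 3.49 between genes. The share near gene ends was lowest in DC replicate 1, at 9.71%, which also had the most peaks.

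The first comparison asked whether the enhancer variants altered C/EBPα binding at the enhancer itself. One region on chromosome 2, from 45279456 to 45279868 (mm10), lay 162.2 kb beyond the Zeb2 gene end and had the highest pileup of the window in WT. Its pileup was 338 and 318 fragments in WT replicates 1 and 2, 100 in DC replicate 1, and 357 and 243 in DE replicates 1 and 2. DC replicate 2 had no peak there. After scaling, DC replicate 1 was 5.52-fold lower than WT replicate 1 (95% interval 4.41 to 6.97). Of the 37017 regions called in both libraries, 22 had a DC to WT ratio as low. The 37017 were 46.2% of the regions called in WT replicate 1, and regions without a call in DC replicate 1 had no ratio to count. WT replicate 2 was at least 6.22-fold higher than DC replicate 2, in which up to 35 fragments could go uncalled. That limit assumes a local background as far above the floor as in DE replicate 2. In DE the scaled pileup was 0.876 of WT in batch 1 (0.752 to 1.02) and 0.824 in batch 2 (0.694 to 0.977).

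The DC difference had 1 value per batch and no test between replicates, and its size was tied to the scaling. Scaling by the background floor gave a DC to WT ratio of 0.355 in batch 1 in place of 0.181 and a limit of 3.71-fold in batch 2. For DE against WT, limma over the 25873 regions called in all 4 libraries gave a log2 difference of -0.22 (interval -0.81 to 0.37; adjusted p = 0.999), and with batch as a term the interval was -0.67 to 0.23 (adjusted p = 0.828). That difference was therefore not detectable with these libraries, and with floor scaling the batch 2 ratio was 1.69, on the other side of 1. A call at the region was present in 2 of 2 WT, 1 of 2 DC and 2 of 2 DE libraries. By −log10 q rank, which depends on the local background, this region stood at 119 and 976 in WT replicates 1 and 2. Among the 605 regions whose worse WT rank was 976 or better, it was the only one without a call in DC replicate 2. None of the 605 lacked a call in DC replicate 1. Most of the 605 ranked below this region in WT replicate 1. In DE replicate 1, 1 other of these regions had no call, and in DE replicate 2 none lacked one. At the assumed local background a call at the enhancer region in DC replicate 2 needed 36 fragments, against 4 at the floor. The 605 regions were not matched for background, so the missing call reflects that background as well as the pileup. Of all 31297 regions called in both WT libraries, 4.37% had no call in DC replicate 1 and 17.1% none in DC replicate 2.

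**Figure D1:**
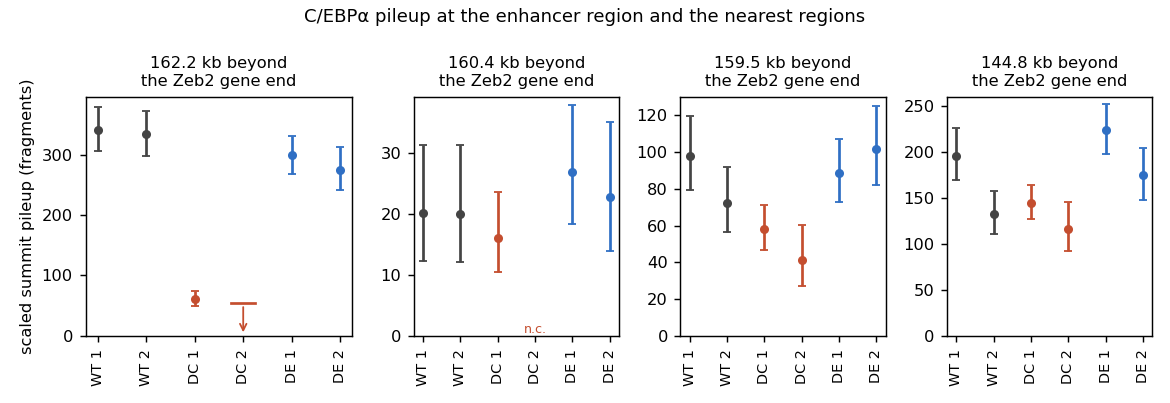
Scaled summit pileup in fragments (vertical axis, linear) of the enhancer region and 3 neighbouring regions in each of the 6 libraries (horizontal axis). Points are values, bars are 95% Poisson intervals, the arrow marks the upper limit for DC replicate 2 (53.7) and n.c. means no call. The DC points at the enhancer region lie under those of WT (341 and 334) and DE (299 and 275).

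Along the Zeb2 locus the DC to WT ratios of the regions next to the enhancer were nearer to 1 and lay within the spread of other regions. The region from 45276685 to 45277185, 159.5 kb beyond the gene end, had DC to WT ratios of 0.593 (0.442 to 0.796) and 0.571 (0.352 to 0.903) in batches 1 and 2, and 16.6% and 8.49% of the regions compared were as low. With floor scaling these ratios were 1.16 and 0.959, so no direction is given for it. Its DE to WT ratios were 0.906 (0.681 to 1.21) and 1.41 (1.02 to 1.95). The region at 144.8 kb, from 45261918 to 45262496, had DC to WT ratios of 0.738 (0.608 to 0.898) and 0.880 (0.653 to 1.18), with 30.3% and 38.0% of regions as low, and of 1.45 and 1.48 with floor scaling. Its DE to WT ratios were 1.14 (0.945 to 1.38) and 1.32 (1.03 to 1.68). A weaker window region, from 45277682 to 45277996, had a DC to WT ratio of 0.796 in batch 1, with 36.0% of regions as low. With floor scaling that ratio was 1.56. The region had no call in DC replicate 2. Inside the gene, the region from 45085664 to 45085949 had ratios of 0.357 and 0.626 in DC and 0.576 and 0.431 in DE (0.699, 1.05, 0.603 and 0.885 with floor scaling). The region from 45114001 to 45114244 was called in both WT libraries, in DC replicate 1 and in neither DE library. A weak region at the gene end, from 45117195 to 45117583, was called in both WT libraries (pileup 11 and 6) and in no DC or DE library. A region from 44952828 to 44953376, beyond the other end of the gene, was called in both DC and both DE libraries and in neither WT library. Its scaled pileups were 26.6 and 19.9 in DC and 37.6 and 22.7 in DE. Of 12 locus regions called in both WT libraries, both DC libraries kept 1 of 3 inside the enhancer window and 6 of 9 outside it (Fisher's exact test, two-sided p = 0.523), and both DE libraries kept 3 of 3 and 7 of 9 (p = 1.0). The p-values rest on few regions, and the DC share kept in the window less that outside, -33.3 percentage points relative to WT, was 4.76 with batch 2 alone and 61.9 with batch 1 alone.

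**Figure D2:**
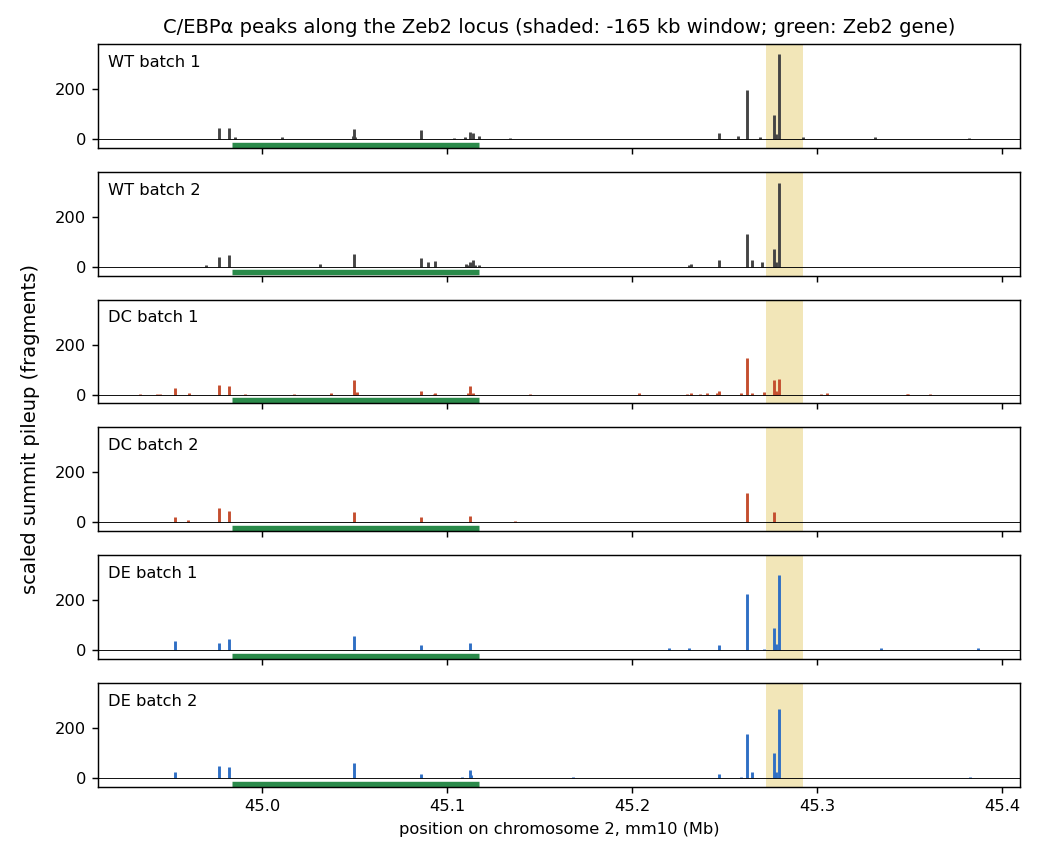
Position on chromosome 2 in Mb (mm10, horizontal axis) against scaled summit pileup in fragments (vertical axis) for every peak of the Zeb2 locus, 1 panel per library. The green bar is the Zeb2 gene and the shaded band the enhancer window; the tallest line of the window stands at 341 and 334 in WT and at 61.8 in DC replicate 1, and is missing in DC replicate 2.

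The second comparison asked how C/EBPα binding differed between DC and WT elsewhere. With batch as a term, 739 regions rose and 275 fell in DC among the 23480 called in all libraries (limma, adjusted p under 0.05). Without the batch term 0 regions passed, with 1873 at an unadjusted p under 0.05. Regions lacking a call in any library were not tested, here or in the comparisons of DE below. Among them was the enhancer region, which had no call in DC replicate 2. The counts thus leave out regions that fell, or rose, so far that a genotype lacked a call. The regions with the smallest adjusted p that rose included those near Prl2c3, a prolactin family gene (72.3 kb away; log2 difference 2.90 ± 0.30 SE, n = 2 per genotype), Thsd4 (2.27 ± 0.27) and the claudin gene Cldn16 (15.1 kb away; 2.54 ± 0.31). A region in Prkch, a protein kinase C gene, also rose (2.25 ± 0.25). Regions that fell included Arhgap22 (-2.51 ± 0.33) and the chemokine genes Ccl5 (4.19 kb away; -2.12 ± 0.36) and Ccl2 (12.5 kb away; -1.99 ± 0.40). So did those of Slamf9 (2.30 kb away; -1.89 ± 0.32), the interleukin-1 receptor kinase gene Irak2 (-1.74 ± 0.33) and the tetraspanin gene Cd82 (-2.05 ± 0.38). Each of these had an adjusted p of 0.000406 or less with the batch term and of 0.0801 or more without it.

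Among the gene lists, that of neutrophil and monocyte genes had 88 regions within 10 kb of 29 genes, of which 8 rose and 1 fell in DC, or 9 and 1 adjusted over the list alone. The 8 lay at S100a9 (3 regions, log2 2.03 ± 0.27, 1.79 ± 0.26 and 1.18 ± 0.23) and S100a8 (1.39 ± 0.30), the subunits of neutrophil calprotectin, and at the monocyte antigen gene Ly6c2 (2.16 ± 0.36 and 1.23 ± 0.37). The others were at Ms4a3 (1.07 ± 0.28) and at Cebpe, a factor of granulocyte maturation (0.85 ± 0.23). The 1 that fell was at the chemokine receptor gene Cx3cr1 (-0.86 ± 0.22). S100a8 and S100a9 are neighbours on chromosome 3, with best WT regions that start at 90668665 and 90686663, so their regions are not separate loci. Among all 23480 regions tested, 739 rose and 275 fell. The list as a whole did not stand apart from other regions (camera adjusted p = 0.715; adjusted p = 0.865 with an estimated correlation). Of 21 cDC1 regions, 1 at Batf3, a factor required for cDC1, fell (-1.37 ± 0.32) and 1 at the cDC1 marker Naaa rose (1.82 ± 0.40), with the same counts adjusted over the list alone. Single regions that changed included those at Foxo1 (1.24 ± 0.30) and Dntt (-1.05 ± 0.33) of the B lymphoid list, Epor (1.35 ± 0.40) of the erythroid list and Etv6 (-1.31 ± 0.41) of the stem and progenitor list. Adjusted over the list alone, each of these but Etv6 passed. No region of the cDC2, pDC, T and NK, mast, basophil and eosinophil, or housekeeping lists passed over all regions. Adjusted over the list alone, 1 region of the mast, basophil and eosinophil list rose and 1 fell. No list passed by camera in DC, where the smallest adjusted p was 0.204, and 0.865 with an estimated correlation.

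The counts for DC depended on single libraries. Leaving out 1 library, with the lone sample of its genotype assumed to vary like the others, gave 277 that rose and 51 that fell without WT replicate 2, 167 and 62 without DC replicate 1, 152 and 42 without DC replicate 2, and 597 and 148 without WT replicate 1. Of the regions named, those at Prl2c3, Thsd4, Cldn16, Prkch, Arhgap22, Ccl5 and Slamf9, 2 at S100a9 (2.03 and 1.79) and 1 at Ly6c2 (2.16) passed in each of these runs. Without DC replicate 2 the following did not pass: Irak2 (-1.27, adjusted p = 0.164), Cd82 (-1.56, 0.0919), Ccl2 (-1.37, 0.216), Batf3 (-1.32, 0.137), Naaa (1.42, 0.245), Cx3cr1 (-0.70, 0.425), S100a8 (1.11, 0.297), Ms4a3 (1.15, 0.198) and Cebpe (0.59, 0.601). The same held for the S100a9 region with 1.18 (0.81, 0.344), the Ly6c2 region with 1.23 (1.28, 0.298), Foxo1 (1.28, 0.153), Dntt (-0.40, 0.856), Epor (1.10, 0.478) and Etv6 (-1.14, 0.441). Scaling by the background floor moved the median log2 difference of all regions to 0.84 and left 682 that rose and 0 that fell (5170 at an unadjusted p under 0.05), so every fall is stated relative to the median region. With the DC and WT labels exchanged in batch 2, 0 regions passed, against 1014 in the real pairing. The exchange puts shared differences into the residual spread, so this is no rate of false calls.

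**Figure D3:**
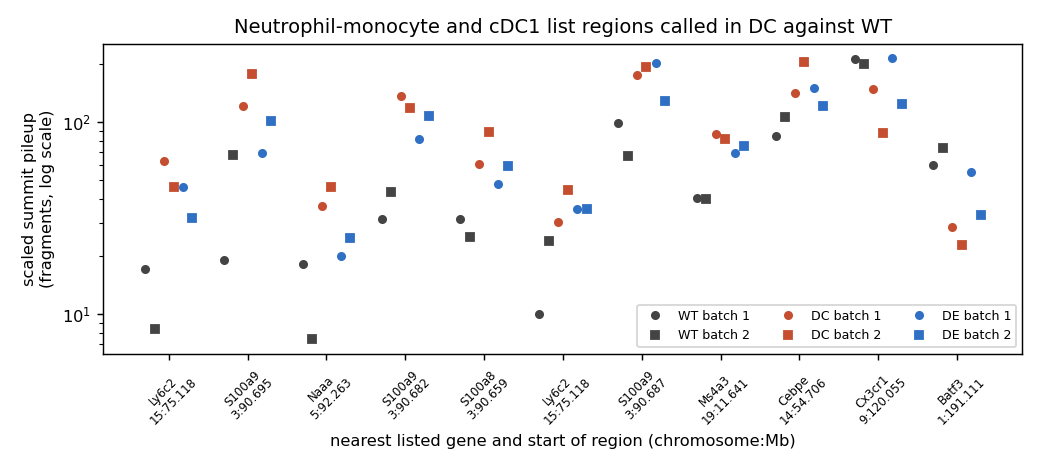
Scaled summit pileup (vertical axis, log scale, fragments) of the neutrophil and monocyte and cDC1 list regions called between DC and WT, 1 column per region, with the listed gene and the start of the region in Mb. Circles are batch 1 and squares batch 2. At S100a9 (90682032) WT had 31.3 and 43.1 and DC 135.9 and 118.1, and at Batf3 WT had 59.5 and 73.5 and DC 28.4 and 23.0.

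The third comparison set DE against WT. With batch as a term 263 regions rose and 62 fell in DE, and without it 0 passed, with 1143 at an unadjusted p under 0.05 (limma). Those that rose included the regions near Prl2c3 (2.67 ± 0.30) and in Tbc1d16 (1.57 ± 0.19), Thsd4 (2.07 ± 0.27) and Asic2 (2.75 ± 0.34), an acid-sensing ion channel gene. Those that fell included the regions near Il1a, the gene of interleukin-1α (1.41 kb away; -2.30 ± 0.44), and in Kcnma1 (-1.84 ± 0.36), Arhgap22 (-1.68 ± 0.33) and the clock gene region near Nr1d1 (7.99 kb away; -1.54 ± 0.33). Of the 88 neutrophil and monocyte regions 4 rose and 0 fell, or 7 and 1 adjusted over the list alone: 3 at S100a9 (1.35 ± 0.26, 1.00 ± 0.23 and 1.21 ± 0.27) and 1 at Ly6c2 (1.67 ± 0.36). The set test gave an adjusted p of 0.681, and of 0.739 with an estimated correlation. In the cDC1 list 1 region fell, at Nfil3, a factor of cDC1 development (-0.89 ± 0.24, adjusted p = 0.0356), or 1 rose and 1 fell adjusted over the list alone. No region of the other lists passed.

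The DE counts fell to 92 that rose and 5 that fell without WT replicate 2, to 42 and 11 without DE replicate 1, and to 72 and 21 without DE replicate 2. Prl2c3, Tbc1d16, Asic2 and Thsd4 passed in every such run. The regions named as lower, and those of S100a9, Ly6c2 and Nfil3, each failed in at least 1. Without DE replicate 1 the adjusted p was over 0.05 for Arhgap22 (adjusted p = 0.109), Kcnma1 (0.0536), Nr1d1 (0.276), Nfil3 (0.653), Ly6c2 (0.141) and S100a9 (0.0536, 0.305 and 0.372), and without DE replicate 2 for Il1a (0.113). Floor scaling moved the median to 0.55 and left 6 that rose and 0 that fell (1732 at an unadjusted p under 0.05). With labels exchanged in batch 2, 0 regions passed, against 325, which again is no rate of false calls.

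DC and DE differed from WT in the same direction at many regions. Of the regions called, 218 rose and 35 fell in both variants and 0 went opposite ways. The log2 differences of the variants correlated across regions (Pearson r = 0.68, regions not being independent replicates), but both were taken against the same WT libraries. Simulations with no effect gave r = 0.50, and as many top-ranked regions shared a mean of 113 higher (at most 132 in 100 simulations) and 26.1 lower (at most 36). Called directly, DC against DE differed at 7 regions with batch as a term and at 0 without (558 at an unadjusted p under 0.05; limma). Prkar1b, a regulatory subunit of protein kinase A (1.59 ± 0.32), and 2010003K11Rik (1.29 ± 0.28) were higher in DC. Lower in DC were Xxylt1 (-1.80 ± 0.36), Slamf9 (2.30 kb away; -1.59 ± 0.32), Rab7b (-1.12 ± 0.24), Naip2 (-1.24 ± 0.27) and Dynlt1b (-1.21 ± 0.26), with adjusted p over the 7 from 0.0316 to 0.0472. Floor scaling moved the median to 0.30 and left 0 that were higher and 0 lower (404 at an unadjusted p under 0.05). Exchanging labels in batch 2 gave 6 regions, against 7 in the real pairing. Leaving out DC replicate 1, DE replicate 1 or DE replicate 2 gave 0 regions, leaving out DC replicate 2 gave 0 higher and 4 lower, leaving out WT replicate 1 gave 14 and 17, and leaving out WT replicate 2 gave 15 and 16. No list region passed over all regions, and adjusted over the list alone 2 were higher and 1 lower in the mast, basophil and eosinophil list and 1 lower in the B lymphoid list. The smallest list-level camera adjusted p was 0.247, and 0.989 with an estimated correlation.

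**Figure D4:**
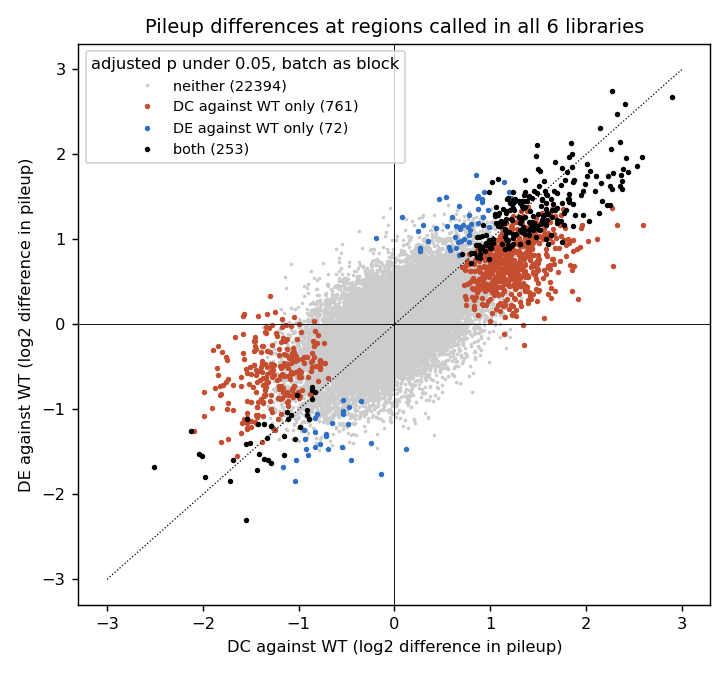
Log2 difference in pileup of DC against WT (horizontal axis) and of DE against WT (vertical axis) at the 23480 regions called in all libraries. Colours mark the regions passing with batch as a term in DC only (761), DE only (72) or both (253), and the dotted line marks equal differences. The 253 lie in the upper right and lower left of the plot.

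The presence or absence of calls was also compared between genotypes. Regions called in both DC and neither WT library numbered 3944, led by regions whose nearest genes were Sfi1 (5.09 kb away), Pcdh15 (139 kb), Commd10 (78.3 kb), Stpg2 (159 kb), Pam (29.0 kb) and Thsd4 (inside it). A further 1012 were called in both WT and neither DC library, led by Arhgap22, Siglec1 (a macrophage adhesion receptor; 4.14 kb away), Tbc1d1, Map2k3 and Gnptab. For DE the numbers were 2195, led by the same regions of Thsd4, Sfi1, Pcdh15 and Stpg2, and 1654 the other way, led by an unplaced contig, Hecw2, Parp8 and Ube2d2a (7.67 kb away), with the Zeb2 region at 45114001 the tenth. Between the variants, 2648 regions were called in both DC and neither DE library, led by Tacc2, Rph3a (3.81 kb away) and Dnah6, and 716 in both DE and neither DC library, led by Ppp2r5e and Ctsc (46.6 kb away), with 3 regions 9.90 to 88.3 kb from Gm52481 on chromosome Y among the first 10. Other pairings gave numbers of the same order. The 4 WT and DC libraries split by batch gave 4943 and 1311 regions and split crosswise 305 and 4112. WT and DE gave 1501 and 4114 by batch and 1353 and 997 crosswise, and DC and DE gave 3712 and 1252, and 4703 and 244. With lists of equal length the DC and DE numbers were 1544 and 1449. With 1 library per genotype the counts ranged from 13818 to 130698, the latter for DC over WT in batch 1.

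Peak number did not separate the genotypes. DC had 2.07 times the peaks of WT in batch 1 and 0.882 times in batch 2, DE had 0.639 and 1.01 times, and DC had 3.24 and 0.874 times those of DE. Group means were 69510 ± 17777 peaks in WT, 110082 ± 84656 in DC and 54958 ± 3512 in DE (SD, n = 2). Exact two-sided permutation tests gave p = 1.0 for DC against WT, 0.667 for DE against WT and 1.0 for DC against DE, where the smallest p possible was 0.333. Within batches, an exact sign-flip test gave p = 1.0 for each, where the smallest possible was 0.5. DC replicate 1 alone held 113235 regions called in no other library, 67.5% of its own. Of the 259446 regions 76.7% were called in 1 library and 9.05% in all 6. The Jaccard overlap averaged 0.319 between libraries of the same genotype, 0.347 between those of the same batch and 0.312 between the rest. By exact permutation, 9 of the 15 ways to pair the libraries gave a difference as large as the real one of -0.0106 (exact one-sided p = 0.6). Within batches the real pairing had the largest difference of the 6 possible (exact permutation p = 0.167, the smallest that can occur), so overlap by genotype was not settled. Overlaps with DC replicate 1 ran from 0.176 to 0.228 and the others from 0.283 to 0.480.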

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

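Of the tests in this part, that of a shared control library was chosen after the background values were seen.

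The peak caller's local background at the enhancer region, which enters the −log10 q, the ranks and the calls but was itself not compared between genotypes, stood far above the floor of the library in batch 2. It was 45.7 times the floor in WT replicate 2 and 53.3 times in DE replicate 2, against 1.69, 1.89 and 3.09 times in the batch 1 libraries of WT, DC and DE. The value could not be recovered for DC replicate 2, which had no call there, and no control sample gave a level to set beside it.

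Whether a C/EBPα library was carried over into the batch 2 control cannot be told. In each batch 2 library, regions within 1 kb of a gene end had more background than other regions at matched pileup. The ratio was at least 1.79 (interval 1.67 to 1.83). A copy added to an ordinary control could leave such a ratio, which was at least 1.44 in batch 1 too, so it decides nothing. At pileups like that of the enhancer region the median background over floor was 11.8 in WT replicate 2 and 9.77 in DE replicate 2. In batch 1 it was 2.54 in WT and 2.32 in DE, and such a copy could give this rise as well. A control library of batch 2 shared by the genotypes is consistent with the background over floor, whose lowest rank correlation within batch 2 was 0.872, against 0.755 to 0.784 within batch 1 and 0.258 to 0.301 between batches. Open chromatin near gene ends cut in that control may add to it, as the ratio reached 2.21 in batch 2, although it was also at least 1.44 in batch 1. What stays open is why the enhancer region exceeded others of like pileup (7 of 163 regions were as high in WT replicate 2, and 9 of 356 in DE replicate 2), and no biological explanation was tested.

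The DE lists held 82 and 65 peaks on chromosome Y in replicates 1 and 2, against 12 and 20 in WT and 24 and 13 in DC, and no comparison was made of chromosome Y on its own.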

How the results depend on the processing

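The alternatives to the scaling of pileups, the fits with batch as a term and the runs without single libraries were chosen after the data were seen. The planned motif search with its alternatives and the count test with its alternatives were not run, for want of a genome sequence and of counts. No overlap value exists without a replicate number, as no pair of the same genotype is left. Unless stated, the cause of a change was not tested.

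With a −log10 q of at least 2 (27 results), summits within 200 bp (12), the authors' merged table (6) and a 5 kb enhancer window (3), the direction, side of the threshold or size was kept in each. With lists of equal length 22 results were kept, and the DC and DE sets moved from 2648 to 1544 and from 716 to 1449 regions. A 1 kb gene window gave 45% for stem and progenitor genes, and a 50 kb window gave 100% for cDC2 and 50% for non-haematopoietic genes. Blocking by batch kept the 4 results on peak number and overlap. All 60 named calls were kept under the stricter q, equal length and summit rules.

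Using 1 batch alone, which leaves 1 library per genotype and no test, the log2 peak number difference ranged from -0.18 to 1.05 for DC against WT, -0.65 to 0.013 for DE against WT and -0.19 to 1.70 for DC against DE. The enhancer call held in 0% to 100% of DC libraries, and the points kept in the window less those outside ranged from 4.76 to 61.9 for DC and from 57.1 to 66.7 for DE (22.2 with both). Sets of regions grew, by construction, to 23678 to 43182 (WT, not DC), 16736 to 130698 (DC, not WT), 19701 to 49434 (WT, not DE), 20063 to 20531 (DE, not WT), 14690 to 130237 (DC, not DE) and 13818 to 21994 (DE, not DC). Occupied shares were 90% to 100% for stem and progenitor, 93.3% to 100% for B lymphoid, 73.3% to 80% for T and NK and 40% to 50% for non-haematopoietic genes.

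At the enhancer region the DC to WT ratio in batch 1 was 0.355 with floor scaling and 0.296 with none, the limit in batch 2 was 3.71-fold with floor scaling, and the DE to WT ratio was 1.06 in batch 1 with no scaling and reversed to 1.69 in batch 2 with floor scaling. A ratio was counted as reversed only where its interval under the main scaling lay wholly on 1 side of 1. Of 31 ratios at other Zeb2 locus regions, DC to WT in batch 1 reversed at 45276685 (1.16, floor scaling) and at 45261918 (1.45 with floor scaling, 1.21 with none). A further 19 moved with floor scaling and 5 with none. Among those, DC to WT in batch 1 also crossed 1 with floor scaling at 45277682 (1.56), 44976521 (1.56) and 44981639 (1.49), as did some ratios in batch 2. Adding batch as a term took the number of differing regions from 0 to 1014 for DC against WT, 325 for DE against WT and 7 for DC against DE. From those fits, floor scaling gave 0 lower for DC against WT, 6 higher and 0 lower for DE against WT and 0 and 0 for DC against DE. Quantile scaling gave 95 lower for DE against WT, and 6 higher and 13 lower for DC against DE. Without single libraries the higher and lower counts ranged from 152 to 843 and 42 to 340 for DC against WT, from 42 to 227 and 5 to 48 for DE against WT, and from 0 to 15 and 0 to 17 for DC against DE. Trimmed mean scaling, autosomes alone and a mean pileup of at least 30 kept each of the 6 counts within 1.5 times.

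Of 68 named pileup differences none reversed. Without batch as a term 68 lost their call, with floor scaling 45 and with trimmed mean scaling 1, and without single libraries between 12 (WT replicate 1) and 26 (DE replicate 1).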

Other observations

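The tests in this part of depth, of loss of the sequence, of the shared WT libraries, of weaker enrichment (3 tests) and of linked blocks were chosen after the result was seen, and that of changed bases before.

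Regions that rose in DC were mostly away from genes' ends: 7.44% of the 739 lay within 1 kb of a gene end (exact binomial interval 5.66 to 9.58), against 23.4% of all 23480 regions tested. The same held for the 263 that rose in DE, at 7.22% (4.41 to 11.1), and for the 275 that fell in DC, at 10.5%. Of the 62 that fell in DE, 21.0% lay there (11.7 to 33.2), which did not differ from all regions by Fisher's exact test (p = 0.764). Whether DC and DE differ from each other in this share was not tested.

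The low pileup at the enhancer region in the DC libraries was weighed against 3 technical explanations. Lower depth or recovery that acts on all regions alike is removed by the scaling, so the share of regions with a ratio as low could not test it. That share was 0.0594% of the regions called in WT replicate 1 and DC replicate 1, which sets the enhancer region apart from most of those regions. Regions without a call in DC replicate 1 have no ratio and are not in the share. DC replicate 2, with a median pileup of 24 at shared regions, was not tested in this way. Loss of the whole sequence from all cells of DC replicate 1 is excluded by the 100 fragments over its summit, far above the floor of 1.11. For DC replicate 2, which had no call there, no value tests such a loss. Changed bases in DC that keep reads from being placed cannot be told apart from weaker binding: the summits of DC replicate 1 and WT replicate 1 lay 9 bp apart, but fragments of 150 to 350 bp reach across any short change, so the limit of 100 bp set beforehand decided nothing. The DC variant itself, which the design names, stays among the open explanations as untested.

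For the shared direction of the DC and DE differences from WT, chance values of the shared WT libraries alone gave a covariance of 0.0591 in simulations, and the measured covariance lay 0.0943 above it, beyond the highest of 100 simulations, but the 35 regions lower in both variants were no more than the 36 that a simulation reached. Weaker enrichment in WT goes with the place of the regions that rose. The signal over floor, lowest in WT in each batch, goes with it too (25.5 against 52.2 in DC and 27.4 in DE, and 37.7 against 65.2 and 78.5). Weaker enrichment would raise the strongest regions most. The strongest away from gene ends (1630 by DC pileup, 1626 by DE pileup) had a median log2 of 0.06 in DC and 0.07 in DE. Their upper quartile was 0.31 in DC, under the lower quartile of 1.18 of the 218 regions higher in both (0.27 and 1.11 in DE). The 218 were chosen for having risen, so this comparison cannot count against weaker enrichment. Of the 218, 62 lay among the strongest by DC pileup and 49 by DE pileup. Regions that fell should also lie near gene ends more often than the 23.4% of all regions, and 10.5% did in DC and 21.0% in DE. Regions that rose lay there less often still (7.44% in DC and 7.22% in DE), so this share decides nothing either. Linked blocks of another strain background would put called regions close together. The share with another called region within 1 Mb was at most 12.9 percentage points above random draws. That was for the regions lower in DC (44.7% against 31.8%), beyond the highest draw of 38.2%. The limits of this test were set after the result, and an excess of neighbours does not give the share of regions that such blocks explain. How much of the pattern they account for therefore cannot be told. A difference in the cells that both variants share, such as another mixture of progenitors within the sort gate, was not tested and may underlie the shared direction. The 1 WT library per batch could not be split to measure the variants against separate controls.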
